A study of Mus musculus with 6 samples.

How the data were processed

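Gene expression was measured in 6 samples of sorted mouse cells, 3 Zfp423-GFP positive and 3 Zfp423-GFP negative, with 1 Illumina 1-colour bead array per sample. Per the labels, the cells came from the stromal vascular fraction (the tissue left after the fat-laden adipocytes are removed) of epididymal fat of male mice aged 5 weeks that carry a Zfp423-GFP reporter. Cells positive for PDGFRβ and negative for CD31 (an endothelial protein) and CD45 (a leukocyte protein) were separated by flow cytometry according to their GFP fluorescence. Per the labels' protocols, RNA was amplified in 2 rounds before biotin labelling. The replicates were described as biological; whether each came from 1 animal or from several was not given in the sources used here.

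The main values were probe signals on a linear intensity scale, deposited without normalization between arrays, each with a detection p-value, per the file headers. GenomeStudio was named in the submitters' processing notes, with its version not given. The authors' second table held intensity values of the same arrays. Its columns shared 1 distribution, with medians of 154.1 or 154.2 on each array, and each column had a rank correlation of 1.000 with the matching non-normalized array, so it was read as quantile-normalized on the linear scale; which software settings made it was not given in the sources used here. A detection p-value compares a probe with the negative control beads of its array, per the deposited file's column names and the usual definition of that column.

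Of the 45281 probes, 34885 had 1 gene symbol in the platform annotation used, 18 had several and 10378 had none. Gene numbers of 34807 of the probes with 1 symbol were found in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That table served for names alone, and no coordinates were used.

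Signals were background-corrected and normalized in limma 3.58.1 (R 4.3.3) with neqc, that is, normexp with the negative control distribution inferred from the detection p-values, an offset of 16, quantile normalization and log2. Probes with a detection p under 0.01 on at least 3 of the 6 arrays, in whichever group, were tested, which left 13727 probes (30.3%) and 8819 genes. The test was limma's moderated linear model (lmFit and eBayes), 2-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05 on the adjusted p. A gene was represented by its tested probe with the highest mean over all 6 arrays. Of the 2537 genes with more than 1 tested probe, 567 had at least 1 probe past the threshold, 200 had every probe past it and 2 had probes past it in both directions.

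Fold changes are GFP-positive over GFP-negative, on the log2 scale, with the standard error (SE) of the limma fit. Where a gene was not detected (detection p of 0.01 or more) on any array of a group, its fold is a lower bound, written "at least"; log2 values printed for such a gene, those under alternatives included, are fitted values set against background and not bounds. The bound sets the mean of the group with signal against the mean, in the other group, of the higher of the probe's own value and the lowest value among detected probes on that array.

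The 31 gene lists, the design, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Zfp423, Pdgfrb, Pecam1, Ptprc, Pdgfra and Pparg, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, and up to 6 members per list by p. Lists with at least 5 tested members (26 of 31) were tested with camera in limma at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run as alternatives. The other alternatives were the authors' normalized values, no background correction, median scaling, 3 other detection filters, a block for the letters that open the sample titles, a replicate block, leaving out each array, an intensity trend with a robust prior, array weights, 2 other thresholds and the mean over a gene's probes.

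The procedure was tested on simulated data made from the array backgrounds with an assumed spread of 15, the GFP-negative means and the fitted probe variances, in 20 runs of 3 against 3 arrays with 200 changed probes each and a median of 15023 tested probes. Of the changed probes that passed the filter, the procedure recovered 7.79% at 1.5-fold, 58.3% at 2-fold and 90.1% at 4-fold. More probes passed the threshold in the data (2144) than were changed per run, and simulated noise was independent between probes. These rates may therefore not carry over. On average 9.38% of the procedure's calls fell on unchanged probes, above the nominal 5%. With an intensity trend and a robust prior this share was 5.36%. In 5 runs without any change it called 0 probes.

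The number of arrays limits the precision. Median raw signals lay between 145.8 and 162.0, and 13068 to 14026 probes per array were detected. The sample titles open with the letters RG (GFP-positive 1 and 2, GFP-negative 1) or KM (GFP-positive 3, GFP-negative 2 and 3), whose meaning was not given in the sources used here; they were treated as a possible batch.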

Results

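Transcript levels were compared between Zfp423-GFP positive and Zfp423-GFP negative cells within the PDGFRβ-positive, CD31-negative, CD45-negative stromal population of mouse epididymal fat, with 3 arrays per group. Zfp423 is a zinc-finger transcription factor of the preadipocyte lineage, and the question was which genes set the cells that carry its reporter apart. Correlations between arrays over the tested probes were 0.982 to 0.990 within the groups and 0.948 to 0.960 between them.

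Zfp423 itself did not differ detectably between the groups at the transcript level. The brighter of its probes (ILMN_3131693) read 7.15, 7.63 and 7.60 on the GFP-positive arrays and 7.12, 7.49 and 7.42 on the GFP-negative arrays (log2), a difference of 0.12 ± 0.17 (SE, 95% interval -0.29 to 0.53; exact permutation p = 0.5, 2-sided, where 0.1 is the smallest possible). With single arrays left out it ran from 0.0054 (GFP-negative replicate 1) to 0.27 (GFP-positive replicate 1). The other probe (ILMN_2469366) differed by -0.02 ± 0.28 (exact permutation p = 1). The positions of these probes on the transcript were not checked, and how closely the reporter follows the transcript in this strain was not given in the sources used here. Both stay open, and the probes do not serve as a check of the sort labels. Of the sort markers, Pdgfrb was detected on all 6 arrays and was higher in GFP-positive cells by 0.58 ± 0.11 (limma, Benjamini-Hochberg adjusted p = 0.0172), by 0.63 within the RG arrays and 0.58 within the KM arrays, which share the letters that open their titles. That call ended without GFP-positive replicate 2 (0.53, adjusted p = 0.0561) or GFP-negative replicate 2 (0.55, adjusted p = 0.0745). Pecam1, which encodes CD31, read 7.80 in GFP-positive and 8.21 in GFP-negative cells, a difference of -0.41 ± 0.23 (limma adjusted p = 0.291). It was -0.64 without GFP-positive replicate 3, -0.23 without GFP-positive replicate 2 and -0.26 without GFP-negative replicate 2. This probe (ILMN_3147074) was detected on all 6 arrays, and its other probes (ILMN_1226690 and ILMN_2700982) on none. None of the 4 probes of Ptprc, which encodes CD45, was detected on any of the 6 arrays. Pdgfra (-0.08 ± 0.11, adjusted p = 0.680) and Pparg, the master regulator of fat cell differentiation (0.22 ± 0.17, adjusted p = 0.443), showed no detectable difference. Within the RG and KM arrays Pdgfra read 0.09 and -0.28 and Pparg 0.02 and 0.59. Single arrays left out moved Pparg between 0.04 (GFP-positive replicate 3) and 0.36 (GFP-positive replicate 1), and Pdgfra between -0.13 (GFP-negative replicate 1) and -0.0064 (GFP-positive replicate 3).

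The populations nevertheless differed widely. The largest rise was that of Esm1, the secreted proteoglycan endocan, which reached 12.62 ± 0.23 (SD, n = 3) in GFP-positive cells, was not detected on any GFP-negative array, and was at least 86.3-fold higher (limma adjusted p = 1.54e-05). Ccn5, a matricellular protein also known as Wisp2, was 54.5-fold higher (log2 5.77 ± 0.27 SE), and Fmod, the collagen-binding proteoglycan fibromodulin, 29.2-fold higher (log2 4.87 ± 0.21). Lyz1 was at least 19.4-fold higher; it is a near-identical copy of the lysozyme gene Lyz2, and cross-binding of their probes was not checked by sequence. Ranked by fitted values, which rest on background where a group was not detected, the other 8 of the 12 largest rises were Dner, Galr2, Fbxo2, the elastic-fibre component Mfap4, Ecrg4, Slc38a5, Art4 and Prss35. Of these, Galr2, Art4 and Prss35 were not detected on any GFP-negative array and were at least 9.66-fold, 6.51-fold and 8.36-fold higher. These 3 bounds lie below measured rises of other genes, such as 13.3-fold for Ccn4. Within the RG and KM arrays Ccn5 was 5.29 and 6.17 higher (log2). The folds depend on the background correction, the lower bounds included. Without it the fitted log2 rises, again set against background for genes not detected in GFP-negative cells, shrank to 5.30 for Esm1, 4.85 for Ccn5, 3.93 for Fmod, 3.18 for Lyz1, 3.79 for Dner, 2.61 for Galr2, 3.24 for Fbxo2, 3.55 for Mfap4, 2.91 for Ecrg4, 2.09 for Art4 and 2.19 for Prss35, all still past the threshold.

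The largest fall was that of Nptx2, a secreted pentraxin, which was not detected on any GFP-positive array and was at least 14.4-fold lower there (limma adjusted p = 0.000242). Ppp2r2b, a regulatory subunit of protein phosphatase 2A, was 13.6-fold lower (log2 -3.77 ± 0.19 SE), and the protease gene Adamts16 was 11.8-fold lower (log2 -3.56 ± 0.55). Dpp4, a cell-surface peptidase that marks interstitial progenitors, was 7.70-fold lower (log2 -2.94 ± 0.53, adjusted p = 0.0127). The Dpp4 call narrowly ended without GFP-negative replicate 2 (-2.93, adjusted p = 0.0514) or GFP-negative replicate 3 (-2.87, adjusted p = 0.0523), and the fall was -2.27 without GFP-positive replicate 3. Leaving out GFP-positive replicate 3 also took Adamts16 to -2.89, still past the threshold. The cytokine gene Csf2 and the guidance ligand Sema3e were not detected on any GFP-positive array and were at least 4.67-fold and 5.46-fold lower. Gch1, Aif1l, Mtcl1, Kcnk13, Rasgef1c and Cdhr5 completed the 12 largest falls by fitted value. Kcnk13, Rasgef1c and Cdhr5 were also not detected on any GFP-positive array (at least 3.03-fold, 2.84-fold and 3.74-fold lower), so their rank rests on background. The measured fall of Efhd1 (6.31-fold) exceeds these bounds, so its order against these genes is not known. Within the RG and KM arrays the falls were -2.58 and -5.09 for Adamts16 and -2.11 and -4.39 for Dpp4. Without background correction the fitted falls of Nptx2, Ppp2r2b, Adamts16, Mtcl1, Csf2 and Sema3e shrank to -2.81, -2.72, -2.91, -1.93, -1.53 and -1.58, and those of Kcnk13, Rasgef1c and Cdhr5 to -1.28, -1.28 and -1.30, all still past the threshold.

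In all, 1395 of the 8819 genes (15.8%) passed the threshold in limma after Benjamini-Hochberg adjustment, 763 higher and 632 lower in GFP-positive cells. By fitted values, 364 of them were at least 2-fold higher and 211 at least 2-fold lower, and 47 were at least 8-fold higher and 6 lower. For genes not detected on any array of a group these values are set against background. The lower bound of a counted gene can therefore lie under the limit. The groups did not overlap for 3219 genes (36.5%), where chance gives 10%. Among the genes past the threshold, 98 were not detected on any GFP-negative array and 59 on any GFP-positive array. At the probe level, 1078 were higher and 1066 lower. With the title letters RG and KM as a block 1137 genes passed. With fewer arrays the number of genes higher fell to 482 and 451 without GFP-positive replicate 1 and 2, and to 465 and 483 without GFP-negative replicate 2 and 3; the number lower was 379 without GFP-positive replicate 2, 223 without GFP-negative replicate 2 and 237 without GFP-negative replicate 3.

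**Figure D1:**
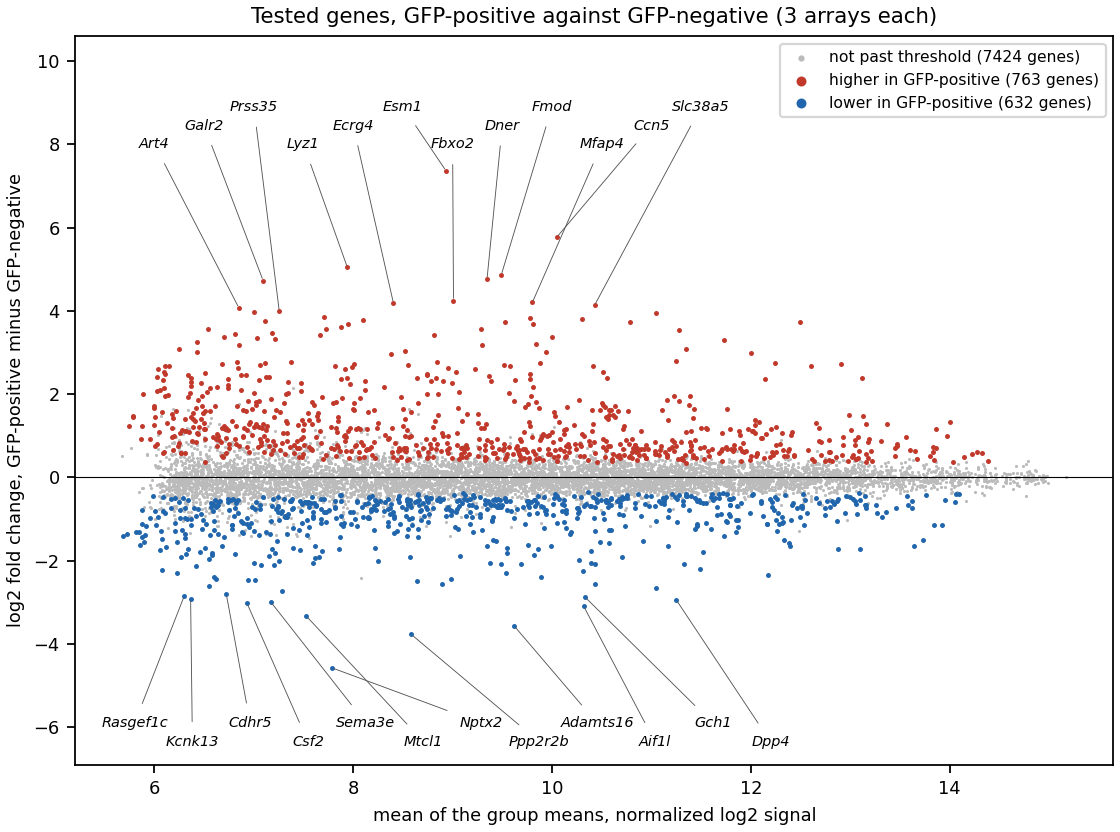
Log2 fold change (GFP-positive minus GFP-negative) against the mean of the group means (normalized log2 signal) for each tested gene, with the 763 genes higher in GFP-positive cells in red, the 632 lower in blue and the rest in grey. The 24 named genes are the 12 largest rises, led by Esm1, and the 12 largest falls, led by Nptx2; values are those fitted, also for genes whose fold is given in the text as a bound.

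Markers of mural cells, the pericytes and smooth muscle cells of vessel walls, were higher in GFP-positive cells. Of 13 tested members 9 rose and none fell (10 rose when adjusted over the list alone), with a median log2 fold change of 1.04, also with undetected members at their bound. The potassium channel subunit gene Abcc9 was at least 4.79-fold higher, the smooth muscle myosin gene Myh11 rose 3.48-fold (log2 1.80 ± 0.22 SE), and the Notch receptor gene Notch3 and its target Heyl rose 2.13-fold and 2.54-fold. Camera gave the list an adjusted p of 1.18e-06, and the adjusted p = 0.162 with an estimated correlation. The median was 0.78 within the RG and 1.20 within the KM arrays, and without background correction the fitted log2 rises of Abcc9, Myh11 and Notch3 were 1.56, 1.19 and 0.69, for Abcc9 against background. Among other contractile-tissue markers, 7 skeletal muscle genes were tested, of which Des, also a mural gene, rose and Tnnt3 fell; the Des call was lost under 7 of 17 alternatives.

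Markers of Dpp4-positive interstitial and fibro-inflammatory progenitors went the other way. Of 17 tested members 12 fell and none rose (12 fell and 1 rose when adjusted over the list alone), with a median of -1.27. Limch1 was 5.90-fold lower (log2 -2.56 ± 0.18 SE), Efhd1 6.31-fold lower (log2 -2.66 ± 0.24), and the hyaluronan synthase gene Has1 5.07-fold lower (log2 -2.34 ± 0.24). Fn1, which encodes fibronectin, was 4.13-fold lower, and Uchl1, not detected on any GFP-positive array, at least 2.98-fold lower (log2 -1.05 without background correction). Pi16, singled out after its value was seen because it marks the same progenitors, read 13.81 in GFP-positive and 13.37 in GFP-negative cells (0.44 ± 0.13, adjusted p = 0.0713 over all genes) and is the member that rose over the list alone; it passed over all genes under 3 of 17 alternatives. Camera gave an adjusted p of 2.40e-06, and the adjusted p = 0.535 with an estimated correlation. The median was -1.19 within the RG and -1.56 within the KM arrays.

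**Figure D2:**
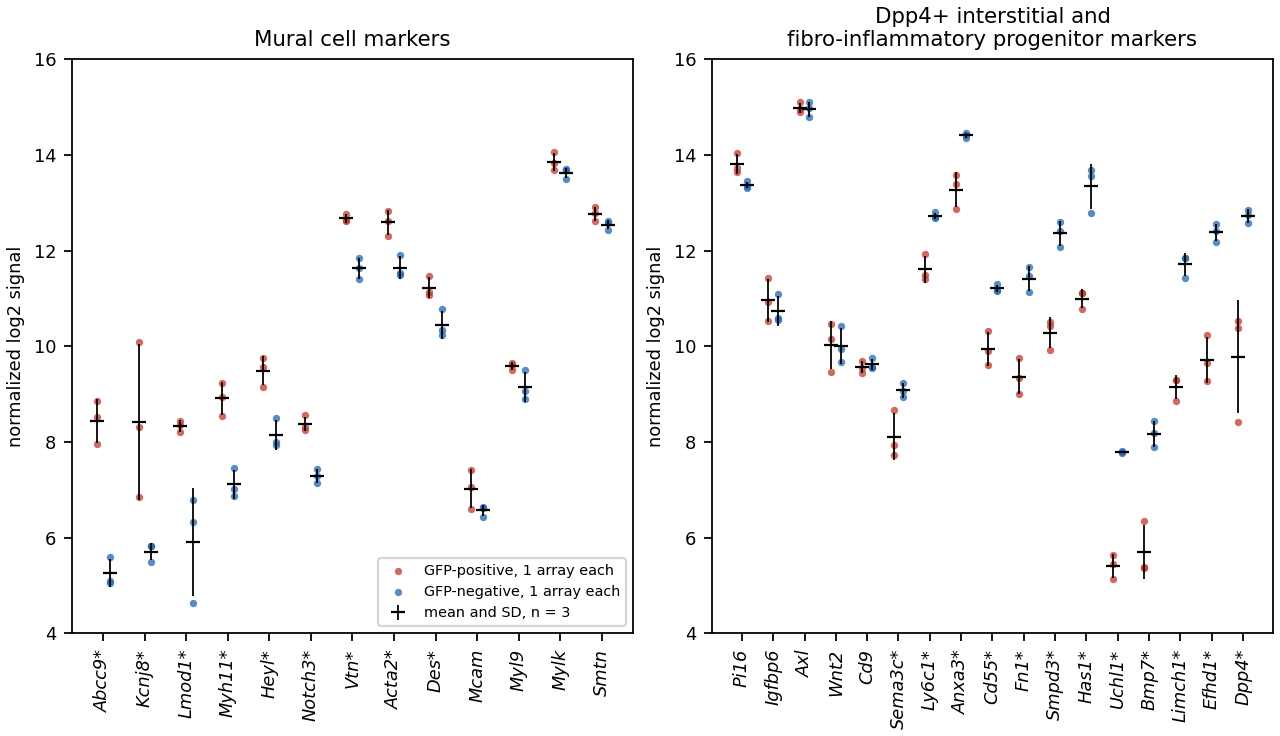
Normalized log2 signal of the tested mural markers (left) and Dpp4-positive progenitor markers (right) on each array, GFP-positive in red and GFP-negative in blue, with the mean and SD of 3 arrays in black; an asterisk marks an adjusted p under 0.05. Of the mural markers 9 of 13 were higher, and of the progenitor markers 12 of 17 lower, in GFP-positive cells; values under about the lowest detected signal of an array (6.06 to 6.35) are not detected.

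Inflammatory cytokines and NF-κB targets were lower in GFP-positive cells. Of 17 tested members 8 fell and 1 rose (11 fell and 1 rose when adjusted over the list alone), with a median of -0.56. The chemokine genes Cxcl2 and Ccl2 were 3.26-fold (log2 -1.71 ± 0.22 SE) and 2.33-fold lower (log2 -1.22 ± 0.17), and Cxcl10 was 2.19-fold lower. The exception was Il33, an alarmin of the interleukin-1 family, which rose 3.24-fold (log2 1.69 ± 0.10). Camera gave an adjusted p of 0.00732, and the adjusted p = 0.597 with an estimated correlation; the median was -0.57 within the RG and -0.51 within the KM arrays. Of 13 interferon response genes 3 fell, Usp18, Rsad2 and Irf7, and none rose (4 fell when adjusted over the list alone; camera adjusted p = 0.0663, or 0.0173 without GFP-positive replicate 2); the Irf7 call was lost under 4 of 16 alternatives, and its fall was -0.62 without background correction. Immediate early and heat shock genes, which report on the stress of cell isolation, had a median of -0.06 and a mean of 0.015 over 15 tested members (camera direction downward, adjusted p = 0.633). Of these Junb fell and none rose (2 fell and 1 rose over the list alone), and the Junb call was lost under 2 of 17 alternatives. Atf3 (-0.48, limma adjusted p = 0.0530) passed as lower and Hspa1a (0.91, limma adjusted p = 0.0579) as higher under 7 alternatives each.

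Among 15 tested Wnt pathway genes 5 rose and none fell (8 rose when adjusted over the list alone), with a median of 0.34. The risers hold secreted proteins that dampen Wnt signals or are induced by them: Ccn5, Ccn4 (13.3-fold, log2 3.73 ± 0.20 SE), Dkk3 (8.50-fold, log2 3.09 ± 0.13) and Sfrp1 (2.21-fold), with Wnt5b the remaining one. The Wnt5b call was lost under 7 of 17 alternatives, and without background correction Ccn4 rose by 3.08 and Ccn5 by 4.85. Camera gave an adjusted p of 0.000452, and the adjusted p = 0.162 with an estimated correlation. That estimate was -0.067, below the preset 0.01, so a higher correlation among these genes does not account for the lost call. The list median was 0.37 within the RG and 0.42 within the KM arrays. Of 8 complement genes 4 rose and 1 fell (5 and 1 over the list alone), with a median of 0.56. C2 and C7 rose 5.21-fold and 5.18-fold, and the complement-inactivating receptor gene Cd55, which is also on the Dpp4-positive progenitor list, was 2.41-fold lower. The complement list had a camera adjusted p of 0.0114, and the adjusted p = 0.338 with an estimated correlation; its median was 0.47 within the RG and 0.61 within the KM arrays.

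Some fibrillar collagen and matrix genes were higher in GFP-positive cells. Of 20 tested members 6 rose and none fell (6 rose and 1 fell when adjusted over the list alone). The matrix gene Fn1, which fell, was not a member and is counted with the Dpp4-positive progenitor markers. The matrix protease gene Mmp3 was 10.3-fold higher (log2 3.37 ± 0.21 SE), the protease inhibitor gene Timp1 3.33-fold, elastin (Eln) 2.54-fold, and the collagen and elastin crosslinking enzyme gene Lox 2.23-fold. The fibrillar collagen gene Col1a2 also rose (limma adjusted p = 0.00394), by log2 0.63 to 0.78 over the alternatives. The list mean was 0.45 but its median 0.04, and the median was -0.06 when arrays were scaled to a common median; it was 0.14 within the RG and 0.05 within the KM arrays. Camera gave an adjusted p of 0.0307, and the adjusted p = 0.535 with an estimated correlation; it was 0.132 with median scaling and 0.0638 without GFP-negative replicate 1. Of 15 basement membrane genes 1 rose, Lamb2, and 3 fell, Lamb1, Col5a3 and Lama4 (3 and 5 over the list alone; camera adjusted p = 0.336). Only Lamb1 kept its call under every alternative; that of Lama4 was lost under 6, of Lamb2 under 5 and of Col5a3 under 1. Without background correction Lama4 and Col5a3 fell by 0.35 and 0.53.

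No list of fat cell differentiation genes passed in camera. Of 13 adipogenic transcription factors 3 rose (Klf5, Zfp467 and Klf15) and 3 fell (Cebpb, Ebf1 and Ebf2), or 3 and 5 over the list alone (camera adjusted p = 0.628). Only Cebpb, 1.57-fold lower (log2 -0.65 ± 0.11 SE), kept its call under every alternative run, and without background correction Klf5 and Klf15 read 0.80 and 0.23 in place of 1.64 and 0.60. None of 10 adipocyte lipid and hormone genes passed over all genes or over the list alone (camera adjusted p = 0.501); Adipoq differed by 0.85 ± 0.52, by 0.28 without GFP-positive replicate 1 and by 1.27 without GFP-positive replicate 2, and Plin4 passed without GFP-positive replicate 1 (1.11, adjusted p = 0.0390). Among 13 committed preadipocyte markers 3 rose and none fell (5 and 1 over the list alone), with Clec11a 11.6-fold (log2 3.53 ± 0.10) and Apoe 5.12-fold higher (camera adjusted p = 0.0566), and the list median was 0.22, or 0.19 with the undetected member at its bound. That list passed under 7 alternatives, without GFP-positive replicate 2 (adjusted p = 0.0369) or GFP-negative replicate 2 (adjusted p = 0.0369) among them, its median was 0.022 within the RG and 0.29 within the KM arrays, and it had an adjusted p = 0.557 with an estimated correlation. Of 14 inhibitors of adipogenesis 3 rose, Wnt6, Dlk1 (4.30-fold) and Nr2f2, and 2 fell, Twist1 and Zfp521 (4 and 3 over the list alone; camera adjusted p = 0.649). None of these 5 kept its call throughout: it was lost under 1 alternative for Wnt6, 3 for Dlk1, 9 for Nr2f2, 3 for Twist1 and 8 for Zfp521. Without background correction Wnt6, Dlk1 and Nr2f2 rose by 0.53, 1.44 and 0.60. Of the thermogenic genes 2 were tested, too few for a list test, and Dio2 was at least 1.98-fold higher (log2 0.86 without background correction).

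Several signalling lists held strong changes without a list call. Of 16 angiogenic and guidance ligands 5 rose and 2 fell (6 and 3 over the list alone; camera adjusted p = 0.0589, or 0.00700 without GFP-positive replicate 2): Angpt2 was 9.09-fold (log2 3.18 ± 0.27 SE) and Vegfc 3.87-fold higher, while Fgf1 was 3.40-fold lower (log2 -1.76 ± 0.17). In the TGF-β list 4 of 12 rose and 1 fell (4 and 3 over the list alone; camera adjusted p = 0.631), with Tgfbi 6.59-fold and Ccn2 2.43-fold higher. In the BMP list 3 of 13 rose and 1 fell (3 and 1 over the list alone; camera adjusted p = 0.501): Id2 and Bmp4 were 3.81-fold and 3.63-fold higher, Bmpr1b at least 5.76-fold higher, and Bmp6 at least 2.44-fold lower. Without background correction Angpt2, Bmpr1b and Bmp6 read 2.57, 1.73 and -0.80, and as means of their probes Tgfbi and Id2 read 3.33 and 1.26 (log2). Calls of Vegfb and Vegfd, both higher, were lost under 5 and 9 of 17 alternatives. That of Tgfbr2, lower, was lost under 8, and that of Tgfb3, higher, under 2. The TGF-β and BMP lists had medians below 0 (-0.15 and -0.11) with means above 0 (0.33 and 0.39) and camera directions upward. Of 12 mesenchymal progenitor markers 4 rose and 2 fell (4 and 3 over the list alone; camera adjusted p = 0.775), with Mgp, the matrix Gla protein, 6.42-fold higher and Thy1 3.26-fold lower; its median was -0.01, its mean 0.14 and its camera direction upward.

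**Figure D3:**
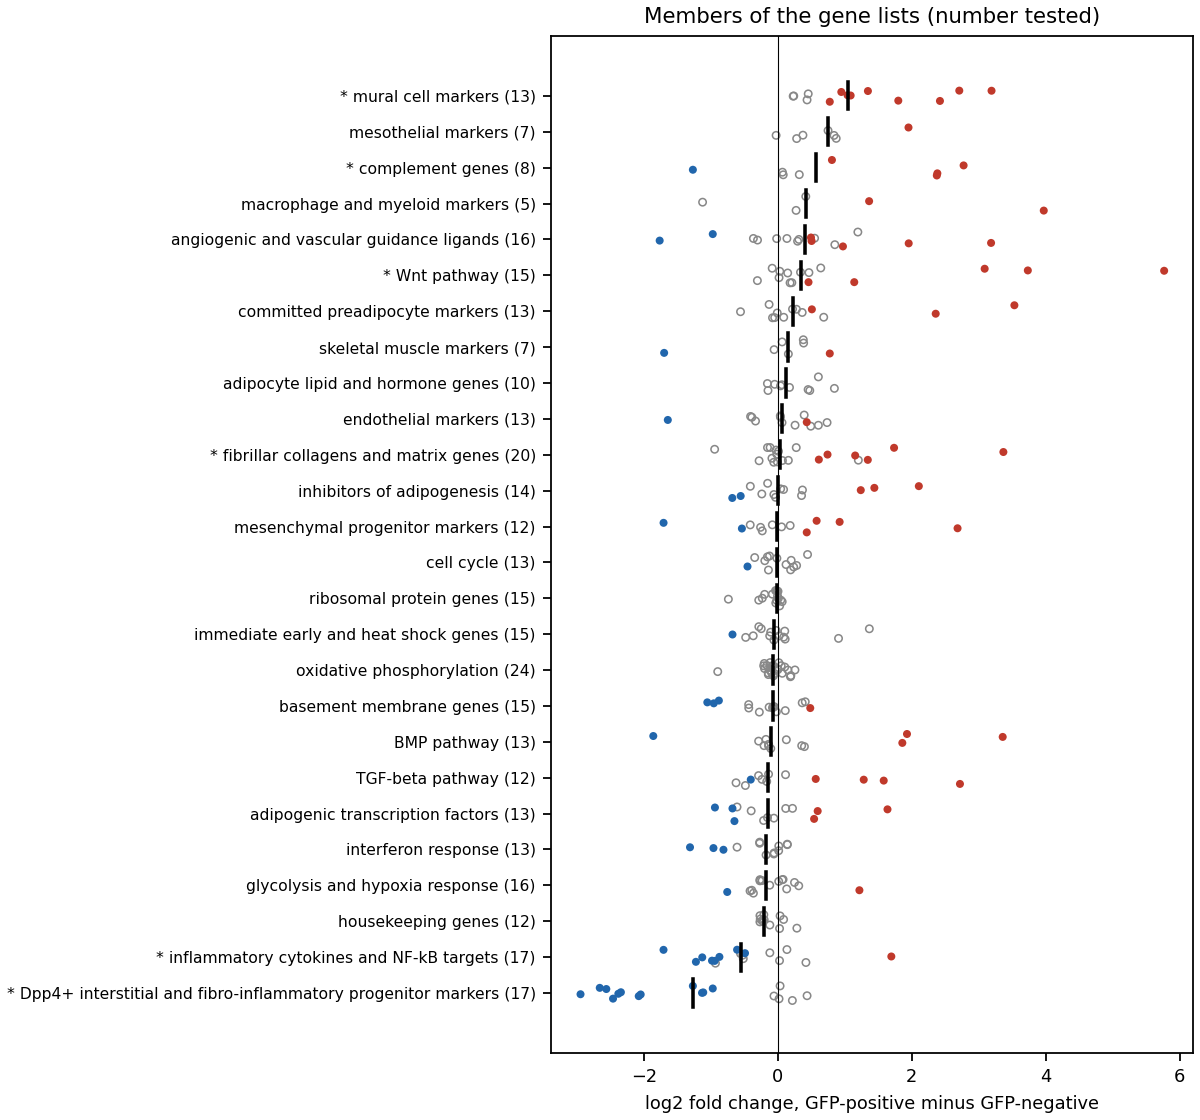
Log2 fold changes (GFP-positive minus GFP-negative) of the members of the 26 tested lists, with the number tested in brackets; filled points passed the threshold over all genes (red higher, blue lower), open points did not, and black bars are list medians. An asterisk marks the 6 lists with a camera adjusted p under 0.05 at the preset correlation, from a median of -1.27 for Dpp4-positive progenitor markers to 1.04 for mural markers.

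No metabolic, proliferation or quality list passed in camera. None of 24 oxidative phosphorylation, 15 ribosomal protein or 12 housekeeping genes passed in limma over all genes or over the list alone (camera adjusted p = 0.633, 0.501 and 0.336). Rps6 (-0.74, adjusted p = 0.0540) passed under 7 alternatives, Gusb under 3, and B2m and Uqcrq under 1 each. Of 13 cell cycle genes Mcm2 fell, and none passed over the list alone (camera adjusted p = 0.844, direction downward, median -0.014, mean 0.0037); the Mcm2 call was lost under 13 of 17 alternatives, and its difference was -0.23 with the authors' values in place of -0.46. Without GFP-positive replicate 3 the camera directions of the oxidative phosphorylation and cell cycle lists turned (adjusted p = 0.946 and 0.778), the latter also without GFP-positive replicate 1 (adjusted p = 0.947). In the glycolysis list of 16, Pfkl rose 2.33-fold and Pfkp fell 1.69-fold (1 and 3 over the list alone; camera adjusted p = 0.501).

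No list of other-cell markers passed in camera, although single members changed. Of 13 endothelial markers Eng rose and Tek fell, the latter 3.12-fold lower (log2 -1.64 ± 0.12 SE; 1 and 1 over the list alone, camera adjusted p = 0.633); the Eng call was lost under 11 of 17 alternatives. Of 5 tested macrophage markers Lyz2 was at least 6.96-fold and Csf1r at least 2.42-fold higher, and none fell (2 over the list alone; camera adjusted p = 0.0589, with an adjusted p of 0.0156 without GFP-negative replicate 3, 0.0467 with median scaling and 0.00749 with a detection p under 0.05, and the direction turned, at 0.946, without GFP-positive replicate 3). Of 7 mesothelial markers Nkain4 was at least 2.18-fold higher (1 over the list alone; camera adjusted p = 0.0663, with an adjusted p of 0.0357 without GFP-positive replicate 3, where Msln and Upk1b also passed). The mesothelial median was 0.75, but 0.71 within the RG and 0.026 within the KM arrays; the macrophage median was 0.42, or 0.80 and 0.36. Skeletal muscle markers gave a camera adjusted p of 0.633 (1 and 1 over the list alone). Lists with under 5 tested members held 3 further changes: the epididymal marker Lcn8 was 11.9-fold higher, the myelin gene Mbp 3.44-fold higher and the platelet integrin gene Itga2b 2.40-fold lower, and the 1 lymphocyte marker tested, Cd79b, differed by -0.80 ± 0.28 (adjusted p = 0.106), by -1.09 without GFP-positive replicate 3 (adjusted p = 0.0218) and by -0.54 without GFP-positive replicate 1. The Itga2b call was lost under 1 alternative. Of the other 13 epididymal markers with a probe, 12 were detected on no array. Without background correction the fitted values of Lyz2, Csf1r, Nkain4, Lcn8, Mbp, Itga2b and Cd79b were 2.06, 0.63, 0.79, 2.16, 0.97, -0.71 and -0.29.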

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

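The alternatives were chosen before the data were examined; the slide block was not run because the files used here name no slides. Of the 24 genes with the largest changes, 23 kept their call under every alternative that tested them, and Dpp4 is the other. Those not detected on any array of a group, such as Esm1 and Nptx2, were tested under 13 alternatives, against 17 for genes such as Ccn5. Leaving out an array of the group with signal took them out of the filter, so that alternative could not end their calls. Of the 113 named genes past the threshold, 81 did so, and no named gene past the threshold changed sign. The groups did not overlap for any of the 1395 genes past the threshold, so leaving out an array could not turn a sign. Genes near the background are limited by signal: the authors' processed values, with no background subtracted, gave Esm1 5.30 in place of 7.37, less than the printed lower bound of 86.3-fold, which holds only with the background correction used. Scaling moved the median of all tested probes from -0.05 to between -0.07 and -0.03. Over all alternatives, gene values kept their direction and side of the threshold 3028 times, went past it 90 times, fell short of it 168 times and turned 18 times; list values did so 401, 25, 9 and 7 times. For changes described here, the cause was not tested, except where fewer arrays, probes or a stricter or looser threshold are the alternative itself.

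Numbers of genes and probes past the threshold moved as follows. With no filter 690 probes and 409 genes were lower. At an adjusted p under 0.1, 1694 probes and 1006 genes were lower. At least 2-fold by fitted values, 519 probes and 364 genes were higher, 319 and 211 lower. The intensity trend with a robust prior, which kept closer to the nominal error rate in simulation, gave 929 genes higher and 807 lower, and 1320 of the 1395. The authors' values gave 1696 genes, 1329 of them shared, and no background correction gave 1697, also with 1329 shared. These alternatives gave nearly the same values, and tallies over the alternatives count both. Leaving out each array gave 639 to 969 probes higher and 359 to 879 lower, and 451 to 693 genes higher and 223 to 534 lower. The share of genes higher went from 54.7% to 67.6% without GFP-negative replicate 2 and 67.1% without GFP-negative replicate 3.

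Replicate numbers showed no sign of pairing the samples: deviations from the group means correlated at -0.0700, -0.200 and 0.0746 between arrays of the same number. Centring within the groups makes the covariances of an array with the other group's arrays cancel out, so these values cannot exclude such a pairing. The highest correlations across the groups were 0.253 (GFP-positive 2 with GFP-negative 1) and 0.165 (GFP-positive 3 with GFP-negative 2). The titles of these arrays carry the same letters and consecutive numbers. A pairing by title number was not tested and stays open. With the replicate block 637 probes and 383 genes were lower, and Pdgfrb stayed at 0.58 with an adjusted p of 0.0511. Pdgfrb ranged from 0.53 to 0.64 when each array was left out. The block also took the angiogenic list to an adjusted p of 0.0410 and the mesothelial list to 0.0186.

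Calls of gene lists depended on the test. With an estimated correlation 0 lists were higher and 0 lower: mural 0.162, Dpp4-positive progenitor 0.535, Wnt 0.162, complement 0.338, fibrillar collagen 0.535, inflammatory 0.597. The estimates themselves were 0.066 (mural), 0.459 (Dpp4-positive progenitor), -0.067 (Wnt), 0.014 (complement), 0.062 (fibrillar collagen) and 0.277 (inflammatory), against the preset 0.01. The Wnt call was thus lost without a higher correlation. Fry, which does not compare a list with other genes, gave 9 lists higher, with adjusted p of 0.00687 for BMP, 0.00166 for TGF-β, 0.0288 for angiogenic, 0.00126 for committed preadipocyte and 0.00126 for macrophage lists. It gave the interferon list as lower at 0.0355, the inflammatory list as lower at 0.0678 and, in the other direction than camera, the endothelial list at 0.771. A detection p under 0.05 gave 7 lists higher, with 0.0404 (angiogenic), 0.0383 (committed preadipocyte) and 0.00749 (macrophage), and the interferon list lower at 0.0383. No filter gave 0.0125 (angiogenic, higher), 0.0140 (committed preadipocyte, higher) and 0.0120 (interferon, lower). The title letters as a block gave 0.0271 (angiogenic) and 0.0441 (committed preadipocyte), and the mean of a gene's probes 0.0349 (committed preadipocyte). Median scaling gave 0.132 (fibrillar collagen), 0.0467 (macrophage) and, reversed, 0.874 (cell cycle). Detection on all 6 arrays reversed the inhibitors of adipogenesis (0.748). Leaving out each array gave adjusted p of 0.00700 to 0.218 (angiogenic), 0.600 to 0.947 (cell cycle, reversed without GFP-positive replicate 1 or 3), 0.0369 to 0.214 (committed preadipocyte), 0.00507 to 0.0638 (fibrillar collagen), 0.0173 to 0.218 (interferon), 0.0156 to 0.997 (macrophage, reversed without GFP-positive replicate 3), 0.0357 to 0.535 (mesothelial) and 0.507 to 0.946 (oxidative phosphorylation, reversed without GFP-positive replicate 3).

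Signs turned for a few small differences, none past the threshold. The dimmer Zfp423 probe (-0.02) read 0.0079 with the authors' values, 0.0081 without background correction, 0.035 with median scaling, 0.12 with the title letters as a block and -0.19 to 0.31 when each array was left out. Cst11 read 0.027 with median scaling, 0.021 with the title letters as a block and -0.14 to 0.13 with arrays left out, Hba-a1 0.19 with that block and -0.65 to 0.49, Acta1 -0.034 to 0.18, Upk3b -0.13 to 0.87, and Rps2 -0.074 with the mean of its probes and -0.047 with median scaling.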

Other observations

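The tests added in this part were chosen after the results were seen. The mural and Dpp4-positive list calls and the values with an array left out repeat alternatives fixed beforehand. Of 25 tested genes with a collagen symbol, fibrillar chains included, 10 rose and 1 fell in GFP-positive cells, with a median log2 fold change of 0.36 and of 0.28 to 0.36 under the scaling alternatives. It was the 1 family of 273 sharing a symbol stem, each with at least 5 tested genes, that passed in camera (adjusted p = 0.0149; adjusted p = 0.991 with an estimated correlation). The short-chain collagen genes Col8a1 and Col8a2 were 2.74 ± 0.32 and 2.39 ± 0.16 higher (SE, log2), and Col8a2 1.77 higher without background correction. Among chains of the basement membrane collagen IV, Col4a3, Col4a4, Col4a5 and Col4a6 were 1.16, 1.44, 0.55 and 1.56 higher, while Col4a1 and Col4a2 differed by -0.08 ± 0.09 and -0.13 ± 0.10 (limma adjusted p = 0.618 and 0.444). Without background correction Col4a6 was 0.94 higher. The Col4a5 call was lost under 9 alternatives, the other 3 kept theirs. These chains were singled out after their values were seen, and the difference between the chains was not tested.

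Lyz1 and Lyz2 rose together in a population sorted against CD45, and macrophage RNA in the GFP-positive samples would carry other macrophage transcripts with them. Over 19 other macrophage markers the median difference was 0.05478. It cannot decide, because 13 of them, C1qa, Tyrobp and Cd74 among them, were detected on no array. How far a given share of macrophage RNA would raise them needs a macrophage profile, which was not used here. Of the 6 with signal, Mrc1 (1.52), Csf1r (1.36), H2-Ab1 (0.56), Cd14 (0.42) and Laptm5 (0.27) read higher in GFP-positive cells, the first 3 against background. Fcer1g (-1.12) read lower. Only Csf1r passed in limma, and Mrc1 and H2-Ab1 were not tested. Cd14, Laptm5 and Fcer1g had limma adjusted p of 0.305, 0.707 and 0.161. Macrophage RNA stays open. Whether 1 lysozyme transcript bound the probes of both genes cannot be told apart from rises of both: their log2 fold changes differed by 1.074, but neither was detected in GFP-negative cells, so both are fitted against background. A biological difference in lysozyme expression between the populations may remain and was not tested.

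Esm1 is best known from endothelial cells, which the sort was set to exclude by CD31. Endothelial markers were still detected in both populations. Of 16 with a probe, 13 were detected on all GFP-positive and 12 on all GFP-negative arrays. Endothelial RNA as its source would raise the other endothelial markers with it. Over 16 of them the median difference was 0.05141 and the highest 0.74 (Emcn, 0.38 without background correction), against at least 86.3-fold for Esm1, and Pecam1 differed by -0.41 (-0.64 to -0.23 with 1 array left out). These values argue against endothelial RNA as the source of the Esm1 rise; a biological difference between the sorted populations was not tested apart from it.

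Mural markers were higher and Dpp4-positive progenitor markers lower in the same comparison. Unequal shares of the RG and KM arrays would shrink the gap between the list medians within each set of letters. It was 1.967 within RG and 2.755 within KM. Groups did not overlap for any gene past the threshold, so most members of both lists had to keep their sign within RG and KM. The gap therefore could not close, and that it stayed open cannot decide on the letters. Its size was not fixed in this way. Mural medians were 0.78 and 1.20 within RG and KM against 1.04 over all arrays, and Dpp4-positive medians -1.19 and -1.56 against -1.27. A stronger dissociation response in GFP-negative samples would lower immediate early and heat shock genes, whose median was -0.05854 (quartiles -0.27 and 0.10), although Junb fell. Atf3 (-0.48) passed as lower and Hspa1a (0.91) as higher under 7 alternatives each, and Hspa1b as higher under 3. Fry gave the list as lower at an adjusted p of 0.0555. Of the named members, the immediate early genes Junb, Atf3, Zfp36 and Ier2 read lower and the heat shock genes Hspa1a and Hspa1b higher. The median pools both classes. It argues against a fall of the immediate early and heat shock genes as 1 set in GFP-positive cells, and not against a fall of either class alone. With members moving in both directions, a dissociation response of part of them stays open. The mural and Dpp4-positive list calls both end in camera with an estimated correlation (adjusted p = 0.162 and 0.535). A difference in cell type between the sorted populations and differences in amplification between samples were not tested and stay open.

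The real grouping was 1 of the 10 splits of the 6 arrays into 3 and 3, and with 10 splits no share under 0.05 can be reached. It gave 2144 probes, 1395 genes and 6 lists past the threshold, more than any other split. The highest of the others gave 1 probe, 1 gene and 4 lists. Every other split except GFP-positive 1 and 2 with GFP-negative 3 (0 lists) also gave at least 1 list. List calls at the preset correlation thus arose under other groupings too, almost without called genes. Those splits mix the groups unequally, so the GFP difference is not wholly removed from them.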
